A study of Homo sapiens with 6 samples.

How the data were processed

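Total RNA from LNCaP and BicR cells was made into short RNA libraries with an Illumina small RNA kit, per the labels' protocols, and sequenced as 6 libraries. The authors deposited 1 table for the whole series. Its values are estimated counts (expected counts that need not be whole) of reads per miRNA arm or locus, with no further normalization visible in them, and 70.9% of the deposited values are whole. Reads that map to several places appear to have been divided, which is read from the fractions and is stated by no label. The submitters' processing notes name the genome build hg19. The aligner, the miRNA annotation and the counting tool are not given in the sources used here. The treatment protocol in the labels speaks of vehicle or DHT for 24 h, whereas the sample labels give before treatment, 6 h and 24 h, and the sample labels were followed.

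The table holds 1524 named miRNA arms and 3364 numbered candidate loci, 4888 in all, and 1 unnamed row with the column totals, which was left out. Candidate loci took 5.79% to 9.48% of each table total. At least 1 of them repeats the reads of a named arm, so the named arms alone were the main universe, and library sizes are their sums, from 2223128 to 9958644 reads. Expected counts were rounded to whole numbers before all tests. Rows with near-identical counts, within 2% or 1 read in each library, were miR-3689a, miR-3689b and miR-3689e (5p) and miR-500a and miR-500b (5p), and they are treated as sharing reads.

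Libraries were scaled with edgeR 4.0.16 TMM factors (R 4.3.3) over all named arms, and log2 CPM (read counts scaled by library size) used a prior count of 2. Arms needed a mean of 10 CPM and of 10 reads over the 6 libraries, which left 287. For 2 libraries, an arm at least 2-fold apart was counted as a description, and the interval of a ratio is the exact conditional binomial interval at 95%. Against 0 reads, 3 reads stood in for the count, which leaves out the counting error of the other library. For all 6 libraries the edgeR quasi-likelihood test had cell line and time as terms, with 2 residual degrees of freedom and a prior of 6.82. The p-values measure spread between libraries of different times and lines, which are not replicates of 1 condition. Adjusted p-values are Benjamini-Hochberg. The SE of a log2 difference is its size divided by the square root of F.

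The plan written before the data were examined named TMM without saying over which arms the factors are taken. All named arms were used in the first run. Factors from the arms over the floor, a common practice with edgeR, were then tried, the results of both were seen, and the main setting was for a while switched to them. It was put back to the first one run, so that it was not picked by its outcome, and the other is reported as an alternative chosen after seeing the data. Between them the calls between lines went from 108 to 93, the smallest adjusted p at 24 h from 0.362 to 0.253, and the DHT tests had 0 calls under both.

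Named arms followed a rule set at the same time as the plan. It took, per line, up to 10 that were higher and 10 lower at 24 h by 2-fold, in the same direction at 6 h and with an interval excluding no change. It also took up to 10 each way at least 2-fold apart between lines at all 3 times, up to 10 each way changed 1.5-fold in both lines, the 10 smallest p per test, the 10 most abundant, and the members of 17 lists. The lists have 102 entries, of which 100 matched a row and 73 passed the floor. A list's percentile is the place of its median among 10000 random lists of the same size and expression decile. Hairpin positions and hosts come from GENCODE annotation on GRCh38, matched by gene name, which found 283 of the 287 arms. No coordinates of the authors' build are printed.

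Alternatives were totals, DESeq2 1.42.0 size factors and Wald test, floors of 1 and 50 CPM or none, and prior counts of 0.5 and 10. Further ones were each library left out, both treated times together, and no time block. Those added after seeing the data were candidate loci together with named arms and TMM from arms over the floor. With a library left out, its time has 1 library, so such a fit holds that time in 1 line only. The tests were checked on simulated counts drawn from the real means, library sizes and spread, with 200 arms changed. At 24 h the test on 290 simulated arms called 100% of those changed by 4-fold, 89.5% of those changed by 2-fold and 34.8% of those changed by 1.5-fold, and 0 of 225 unchanged ones. The test between lines, on 278 arms, called 57.1% of those changed by 1.5-fold and 3 of 206 unchanged ones (1.46%). In both simulations many arms were changed, which makes the adjusted cutoff easier to pass than where few change. Of single pairs of simulated libraries at 24 h, 57.9% of the arms changed by 2-fold and 0.889% of the unchanged ones were at least 2-fold apart. Figures were drawn with matplotlib.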

Results

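Short RNA was sequenced from 2 prostate cancer cell lines to find miRNAs that respond to androgen. LNCaP is an androgen-sensitive line derived from a lymph node metastasis, and BicR is labelled as prostate cancer without further description. Cells were kept in hormone-depleted serum and then sampled before treatment (0 h) or after 6 h or 24 h with 10 nM dihydrotestosterone (DHT), the most potent natural androgen. Each of the 6 combinations of line and time had 1 library, so single comparisons of 2 libraries have no replicate check, and the intervals given with them are exact 95% intervals that cover counting error only. Reads assigned to named miRNA arms numbered 9014998, 9037546 and 9345479 in LNCaP at 0 h, 6 h and 24 h, and 2223128, 3725411 and 9958644 in BicR. The sample labels call the 0 h libraries before treatment, whereas the protocol speaks of vehicle for 24 h, so whether they were matched in time to the treated ones is open. If they were not, time in culture and DHT cannot be separated. An arm is written by its strand, so that miR-29a-3p is the 3′ arm of the hairpin hsa-mir-29a.

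A few abundant miRNAs, mostly shared, dominated both lines. Each line's own 10 most abundant arms at 0 h, which differ in part, took 62.9% of the named-arm reads in LNCaP and 59.9% in BicR. At 0 h, miR-21-5p made up 9.23% of reads in LNCaP and 7.39% in BicR, let-7a-5p 8.52% and 8.83%, miR-378-3p 6.68% and 10.3%, and let-7c-5p 8.16% and 7.72%. Of 1524 named arms, 287 passed the floor of a mean CPM (read count scaled by library size) of 10 and were compared.

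The first question was which miRNAs differed after 24 h of DHT in LNCaP. Among the 287 arms, 1 was at least 2-fold higher and 1 at least 2-fold lower than at 0 h, and 94.1% lay within 1.5-fold. In simulated pairs of libraries, 2 of 225 unchanged arms were 2-fold apart, and 57.9% of the arms changed by 2-fold were. The simulated spread came from the fit of all 6 libraries, both lines included. In LNCaP it gave the 6 h and 24 h differences a covariance of 0.068, above the 0.0421 observed, so it may be too wide here. The simulated share thus cannot tell whether these 2 arms stand above the noise. The higher one was miR-143-3p, an miRNA abundant in smooth muscle and stromal cells, whose reads went from 151 to 632 (log2 difference 1.85, interval 1.61 to 2.13). Its hairpin lies in an exon of the long non-coding RNA gene CARMN (GRCh38, chromosome 5, 149428918 to 149429023). The lower one was miR-3127-5p, at 119 and 63 reads (log2 difference −1.09, interval −1.58 to −0.67), from an intron of CNNM4 (chromosome 2, 96798278 to 96798353). With a prior count of 10 or with scaling to totals the second was less than 2-fold lower, and neither passed a floor of 50 CPM. At 6 h no arm in LNCaP differed by 2-fold.

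Within that narrow range, the let-7 family, which is linked to differentiation and to restraint of growth, was lower in LNCaP after DHT. All 9 measured family members were below their 0 h level at 24 h (median log2 difference −0.31, the 0.425 percentile of 10000 random lists of matched expression) and at 6 h (median −0.29, percentile 0.01). At 24 h all 9 were lower under each of the 4 scalings tried, although scaling to totals moved the median of all arms in LNCaP to 0.141 at 24 h and 0.121 at 6 h. The differences at 6 h and 24 h share the 0 h library, so they are not separate observations. The members are close in sequence and reads appear to be divided among places they map to, so the members are not independent and the percentiles overstate how rare such medians are. The lowest at 24 h was let-7b-5p, at a log2 difference of −0.82 (interval −0.82 to −0.81). In BicR, 8 of 9 were lower at 24 h (median −0.13, percentile 11.2). In the test over both lines the family had 9 of 9 members lower at 24 h (8 of 9 with totals), 0 passed over all arms and 0 passed when adjusted over the list alone (smallest adjusted p = 0.115, edgeR). Without the LNCaP 0 h library 8 of 9 were lower (smallest adjusted p = 0.761 over the list alone), and without LNCaP 24 h 8 of 9 (0.945).

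In BicR, 1 arm was at least 2-fold higher and 2 were at least 2-fold lower at 24 h, and 92.3% of arms lay within 1.5-fold. The largest difference, in miR-3647-3p, rests on 0 reads at 0 h and 22 reads at 24 h, which is at least 1.57-fold higher when 3 reads stand for the library at 0 h, with an exact interval that begins at a log2 of 0.23. Both bounds lie under 2-fold, so its place among the 2-fold arms rests on the prior count. The RefSeq gene table lists this name as an older symbol of the small nucleolar RNA gene SNORD111B. The lower arms were miR-1247-3p, with 26 and 35 reads in libraries of unequal depth (log2 difference −1.71, interval −2.57 to −1.003), from an exon of the long non-coding RNA gene DIO3OS on chromosome 14, and miR-221-5p, with 978 and 2169 reads (log2 difference −1.07, interval −1.18 to −0.96). Levels of miR-375-3p, an epithelial and neuroendocrine miRNA, were 1.80-fold those at 0 h in BicR (log2 difference 0.85, interval 0.67 to 1.03) and near those at 0 h in LNCaP (log2 difference 0.05). Whether the lines differed in this was not tested.

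The BicR library at 6 h stood farther from its 0 h library than the 24 h library did. Here 6 arms were at least 2-fold higher and 4 at least 2-fold lower, and the median absolute deviation of the log2 differences was 0.44, against 0.28 at 24 h in BicR and 0.19 at 6 h in LNCaP. The stromal miRNA miR-143-3p was 10.8-fold its 0 h level at 6 h, at 31 and 583 reads (log2 difference 3.43, interval 2.94 to 4.03), and back at 0.962-fold at 24 h. Others above 2-fold were miR-3647-3p (84 reads against 0, at least 16.4-fold by the floor of 3 reads, with an exact interval that begins at a log2 of 3.70), miR-3607-3p (log2 difference 2.03), miR-146a-5p (1.47, at 59 and 12 reads), miR-374b-5p (1.14) and miR-33b-5p (1.01). Those lower were miR-1247-3p (−1.50), miR-378-5p (−1.27), miR-221-5p (−1.14) and miR-421-5p (−1.13). Of these 10, miR-3607-3p, miR-374b-5p, miR-378-5p and miR-421-5p were outside the naming rule and were chosen after their values were seen.

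Changes at 24 h common to both lines were asked in 2 ways. Across the 287 arms, which are not independent replicates, the log2 differences at 24 h correlated between LNCaP and BicR with Pearson's r = 0.354 and Spearman's rho = 0.437, and 70.7% had the same sign. Without the 2 arms farthest from the LNCaP median r was 0.379. At 6 h the correlation was −0.00797. No library enters both sides. With arms down to 1 CPM included, r at 24 h was 0.160. No arm was at least 2-fold changed in both lines, where chance overlap of independent lists gives 0.00348 higher and 0.00697 lower. At 1.5-fold, 1 arm was lower in both, miR-221-5p, where such overlap gives 0.293.

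In the blocked test of all 6 libraries, no arm passed a Benjamini-Hochberg adjusted p of 0.05 at 24 h with edgeR (smallest adjusted p = 0.362). An unadjusted p under 0.05 was found for 24 arms, where 14.4 are expected by chance. The residual spread in this test also takes in the 6 h libraries, of which the BicR one stood apart. DESeq2 called 2 arms, and so did edgeR with scaling to totals, in both cases miR-29b-3p (log2 difference 0.70 with DESeq2, adjusted p = 0.0332) and miR-221-5p (−0.90, adjusted p = 0.0196). In the edgeR fit these had log2 differences of 0.71 ± 0.16 (SE) and −0.89 ± 0.21. Without the LNCaP 0 h library, BicR 0 h was the only untreated library, so the 24 h difference no longer rested on both lines. It was then 0.93 for miR-29b-3p and −1.17 for miR-221-5p. In simulated libraries of the same depth and spread, this test called 17 of 19 arms changed by 2-fold and 8 of 23 changed by 1.5-fold. There 225 of 290 arms were unchanged and the others were changed by up to 4-fold. The adjusted cutoff was thus easier to pass than where few arms change. These shares may therefore overstate what the test finds in the real libraries, and they do not exclude shared 2-fold changes.

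The miR-29 family, which represses collagen and other matrix genes, was above its 0 h level in all 3 members and in both lines at 24 h. The median log2 difference was 0.34 in LNCaP (percentile 98.2) and 0.64 in BicR (percentile 99.6), with 3 of 3 above under each of the 4 scalings. In the test over both lines, 0 of 3 passed over all arms and 2 of 3 passed when adjusted over the list alone, miR-29b-3p and miR-29a-3p (smallest adjusted p = 0.00562, edgeR). With totals miR-29b-3p passed over all arms. Without the BicR 0 h library (smallest adjusted p = 0.15) or the BicR 24 h library (0.063), 0 passed over the list alone. At 6 h the median was −0.05 in LNCaP and near 0 in BicR. Whether this family was first picked on these libraries is not known here, so its count is not independent evidence. The hairpins lie in 2 clusters, miR-29b and miR-29c in exons of MIR29B2CHG on chromosome 1 and miR-29a and a second miR-29b copy on chromosome 7.

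The miR-99a, let-7c and miR-125b-2 hairpins share introns of the long non-coding RNA gene MIR99AHG on chromosome 21 (16539089 to 16590325, GRCh38), yet their arms went opposite ways at 24 h. In LNCaP miR-99a-5p was at a log2 difference of 0.44 (interval 0.43 to 0.46) and let-7c-5p at −0.53 (interval −0.54 to −0.53), and in BicR at 0.28 and −0.32. For miR-125b-5p, which also has a copy on chromosome 11, the test over both lines gave 0.38 ± 0.15 (SE). All 3 passed when adjusted over the list alone (smallest adjusted p = 0.0294, edgeR) and 0 passed over all arms. Without LNCaP 0 h, LNCaP 24 h, BicR 0 h or BicR 24 h, 0 passed over the list alone (smallest adjusted p 0.318, 0.143, 0.162 and 0.151). Of the 16 lists with a measured member, 2 had a call over the list alone at 24 h.

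**Figure D1:**
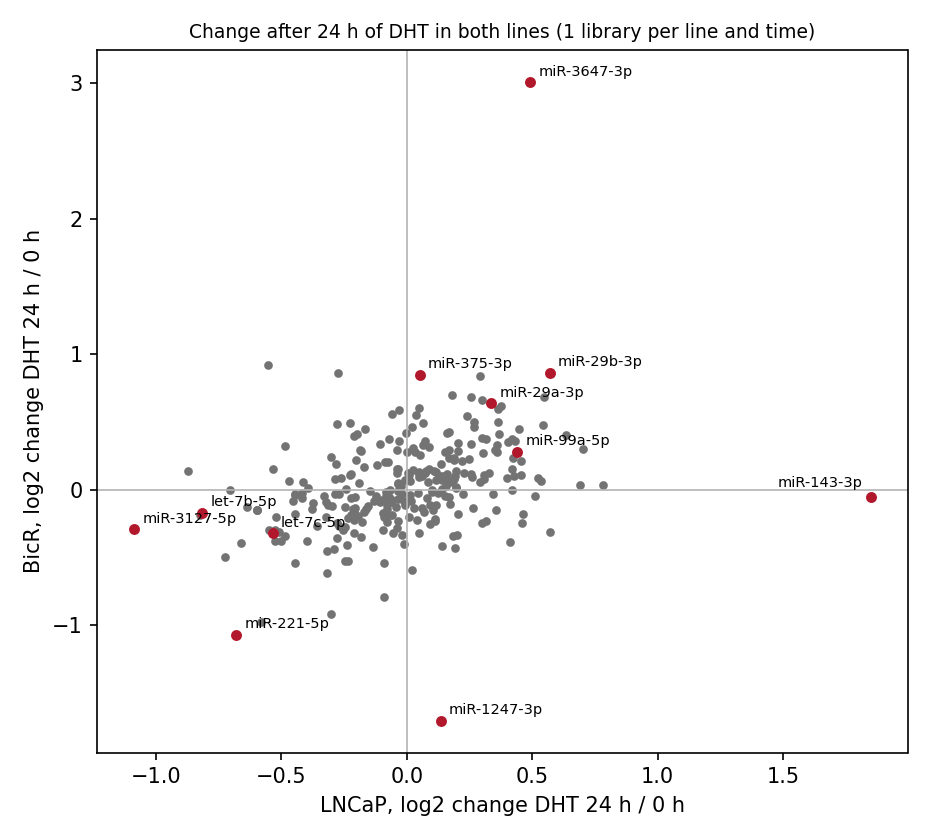
Log2 change after 24 h of DHT in LNCaP (x axis) and BicR (y axis), each point 1 of the 287 arms and each change 1 treated against 1 untreated library, with selected arms in red. Points lean along the diagonal (r = 0.354), with miR-143-3p at 1.85 in LNCaP alone and miR-3647-3p, which had 0 reads in BicR at 0 h, placed by the prior count.

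**Figure D2:**
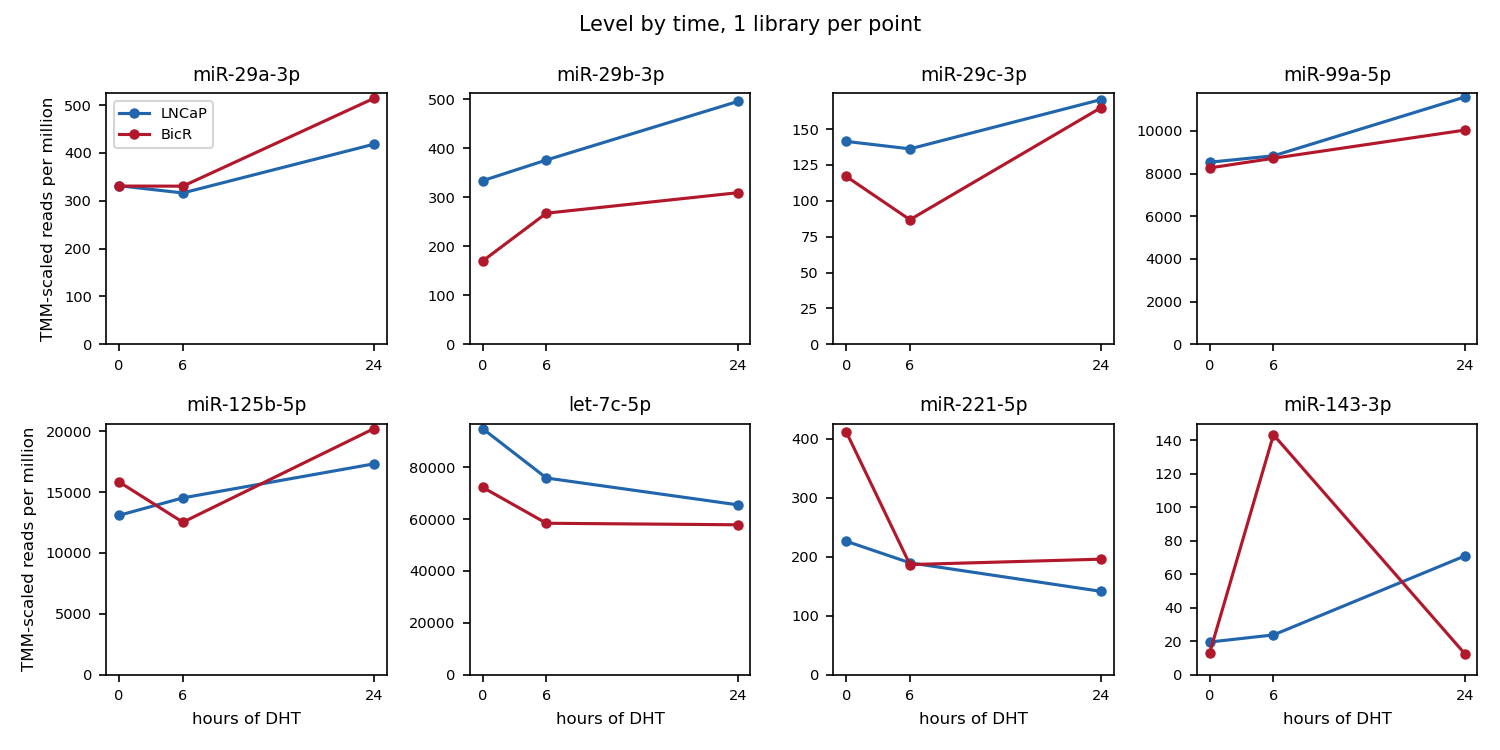
TMM-scaled CPM (y axis, linear from 0) against hours of DHT (x axis) for 8 arms in LNCaP (blue) and BicR (red), with 1 library per point. The miR-29 arms end higher at 24 h than at 0 h in both lines, let-7c-5p and miR-221-5p end lower, and miR-143-3p peaks in the BicR 6 h library, at 143 CPM.

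Lists of miRNAs described as androgen-responsive were compared next. Of 10 measured miRNAs on the androgen-induced list, which includes miR-32-5p, miR-148a-3p and miR-375-3p, 8 were above 0 h in the test over both lines at 24 h. None passed over all arms or over the list alone (smallest adjusted p = 0.183, edgeR), while with totals 2 passed over the list alone (0.0193) and without the 0 h, 6 h or 24 h library of LNCaP 1 did (0.0347, 0.0374 and 0.0212). The median log2 difference was 0.08 in LNCaP (percentile 95.7) and 0.12 in BicR (percentile 98.7). Of the 6 measured on the androgen-repressed list, 3 were above and 3 below (medians −0.05 and −0.09), with 0 passing either way (smallest adjusted p = 0.0589 over the list alone), while with totals 2 passed over the list alone (0.0111), and without LNCaP 6 h 3 did (0.0232). On it, miR-99a-5p and miR-125b-5p had values above 0 h. Both miR-221-3p and miR-222-3p were below 0 h in both lines (medians −0.18 and −0.29) and did not pass (adjusted p = 0.217 over the list alone).

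Of the remaining miRNA clusters and families none had a call at 24 h over all arms or over its list alone, except that with totals the miR-30 family had 5 of 5 above and 1 passing over the list alone (0.0306). Without LNCaP 6 h, 2 arms of that family (0.0217) and 1 of miR-17~92 and paralogues (0.0467) passed over the list alone. The miR-17~92 cluster and its paralogues, which promote proliferation, had 8 of 9 members below 0 h (smallest adjusted p = 0.0719 over the list alone), and 4 of 9 under scaling to totals. The miR-23, miR-27 and miR-24 clusters had 5 of 5 above (adjusted p = 0.497). The miR-30 family had 3 of 5 above (adjusted p = 0.195), the miR-15 and miR-16 family 3 of 6 (adjusted p = 0.322), the epithelial miR-200 family 2 of 5 (adjusted p = 0.549), the miR-183, miR-96 and miR-182 cluster 1 of 3 (adjusted p = 0.27) and the miR-34 and miR-449 family 1 of 2 (adjusted p = 0.231), all over the list alone with edgeR.

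At 6 h, no arm passed the test over both lines (smallest adjusted p = 0.889 with edgeR), 5 had an unadjusted p under 0.05, and DESeq2 called 0. With scaling to totals 3 arms were called, all of them higher, miR-143-3p, miR-3647-3p and miR-3607-3p. With a library left out, 1 library stands for its time, so effect sizes alone are given. The 6 h difference of miR-143-3p was 2.63 without LNCaP 0 h and 2.02 without BicR 0 h. It was −0.13 without the BicR 6 h library, against 2.39 with all libraries. Within a line, the 6 h and 24 h differences share the 0 h library. Their correlation was 0.606 in LNCaP (Spearman's rho 0.634), where simulated unchanged libraries gave a mean of 0.5 and a range of 0.364 to 0.603. The covariance there was 0.0421 against 0.068 simulated. In BicR the correlation was 0.5 (rho 0.301) against 0.543 (range 0.453 to 0.688), with a covariance of 0.113 against 0.0817. That covariance includes miR-3647-3p, with 0 reads at 0 h, at log2 differences of 6.22 and 3.01, both set by the prior count. The covariance without this arm was not computed.

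At 0 h and 24 h the lines differed from each other more than either did after DHT, with a median absolute deviation of the log2 differences of 0.63 and 0.60. At 6 h it was 0.36 between the lines, less than the 0.44 between BicR at 6 h and at 0 h. At 0 h, 21 arms were at least 2-fold higher and 17 at least 2-fold lower in BicR, and 14 stayed at least 2-fold apart in the same direction at all 3 times. Among these 14, the widest gap at 0 h was in miR-146a-5p, a feedback inhibitor of NF-κB signalling, with 3384 reads in LNCaP and 12 in BicR at 0 h, an 81.9-fold lower level in BicR (log2 difference −6.36, interval −7.39 to −5.63). Next among them came miR-10a-5p, which lies beside the HOXB genes, at 13.6-fold lower, miR-190b-5p from an intron of TPM3 (log2 difference −3.37) and miR-375-3p, at 8.61-fold lower. For miR-146a-5p the log2 difference was −4.58 at 6 h and −6.32 at 24 h. At 24 h the levels were 13.9-fold lower for miR-10a-5p, 3.72-fold for miR-190b-5p and 4.95-fold for miR-375-3p. Lower by smaller steps at 0 h were miR-196a-5p (−2.53), miR-1246-5p (−2.31), miR-1269b-5p (−2.30) and miR-210-3p (−1.78), a miRNA induced by hypoxia, which was at −1.07 at 24 h. Higher in BicR at 0 h were miR-618-5p, from an intron of LIN7A on chromosome 12 (7.97-fold, log2 difference 2.99), miR-598-3p from an intron of XKR6 (2.45), miR-3940-3p (1.78) and the miR-3689 group. The a, b and e copies of miR-3689-5p have nearly identical counts and count as 1 uncertain measurement.

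**Figure D3:**
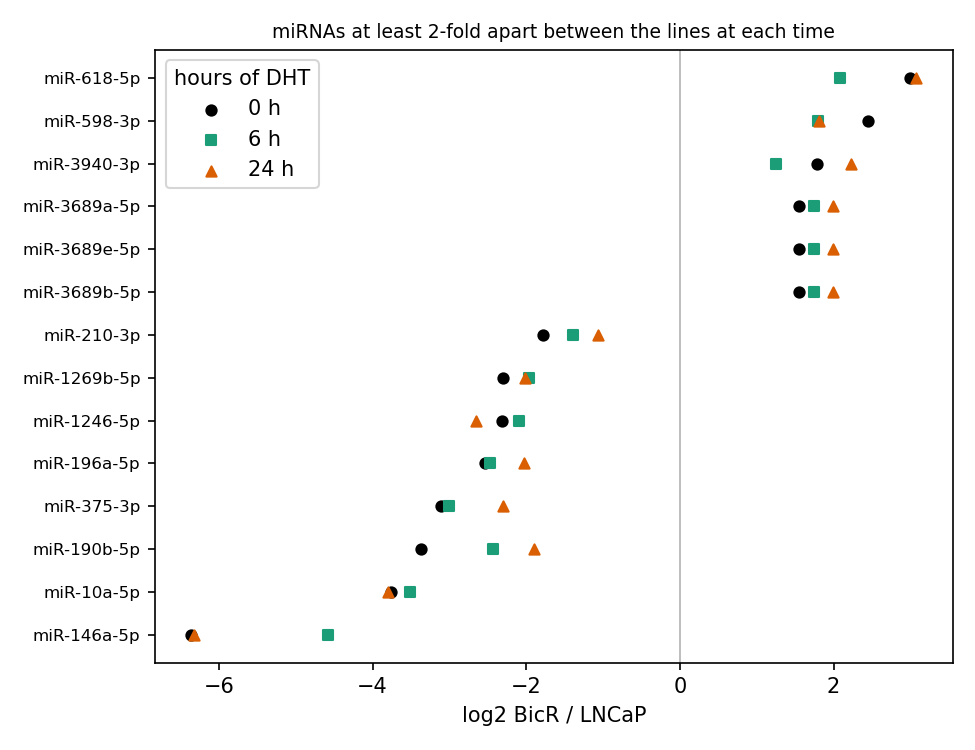
Log2 ratio of BicR to LNCaP (x axis) at 0 h (circles), 6 h (squares) and 24 h (triangles) for the 14 arms at least 2-fold apart at each time (y axis), 1 library per line and time. The ratio for miR-146a-5p is −6.36 at 0 h and −4.58 at 6 h.

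Over all times, with time as a block, 108 of 287 arms differed between lines at an adjusted p under 0.05 with edgeR, 38 higher and 70 lower in BicR. The balance of that split rests on the scaling. It was 51 higher and 42 lower with TMM factors from arms over the floor, 49 and 44 with DESeq2 size factors, 79 and 31 with totals, and 30 and 97 when candidate loci were added, while DESeq2 gave 49 and 48. Under TMM over all named arms the median arm lay at −0.11 at 0 h, and under totals at 0.20. In all 4 scalings of the named arms, 67 arms were called in the same direction, 38 higher and 29 lower. Among them were miR-10a-5p (log2 difference −3.69 ± 0.12 SE, adjusted p = 8.8e-08), miR-375-3p (−2.80 ± 0.17), miR-146a-5p (−5.72 ± 0.36), miR-618-5p (2.72 ± 0.20), miR-195-5p (1.10 ± 0.16) and miR-27b-3p (0.69 ± 0.12). Leaving out 1 library gave between 43 and 139 calls, with 43 without either 24 h library, 52 without BicR 0 h and 59 without LNCaP 0 h.

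By list, miRNAs described as androgen-induced were mostly lower in BicR. Of 10 measured, 9 were lower in the test over all times and 8 passed over all arms, as did 8 when adjusted over the list alone. Under each of the other 3 scalings 6 passed over all arms, counted without regard to direction. Called as lower under all 4 scalings were miR-375-3p, miR-148a-3p, miR-19a-3p, miR-182-5p and miR-23a-3p, but not miR-21-5p, miR-27a-3p or miR-101-3p. The level of miR-32-5p was higher in BicR under each scaling (log2 difference 0.23 to 0.48). Without LNCaP 0 h 2 passed over all arms, without BicR 0 h 1, and without either 24 h library 3. The median was −0.70 at 0 h (percentile 0.075), −0.34 at 6 h (percentile 7.72) and −0.54 at 24 h (percentile 1.6). In the miR-183, miR-96 and miR-182 cluster, 3 of 3 were lower in BicR under each scaling and 3 passed over all arms and over the list alone, 2 with totals. Over all arms 1 passed without BicR 0 h or either 24 h library, and 2 without LNCaP 0 h. The miR-15 and miR-16 family had 5 of 6 higher, with 3 passing both ways, and between 2 and 5 over all arms in the other scalings. Of those 3, miR-195-5p (1.10) and miR-424-5p (0.45) were higher and miR-15a-5p (−0.42) was lower in BicR. The miR-200 family had 5 of 5 lower with 2 passing (1 with totals), and 3 of 5 lower under each of the other scalings. Both miR-221-3p and miR-222-3p were higher in BicR under each scaling, with 1 passing both ways and 2 in the other scalings. Among the rest, over all arms, 3 of 5 passed for the miR-23, miR-27 and miR-24 clusters (2 or 3 in the other scalings), 3 of 9 for miR-17~92 and paralogues (2 in the others), 3 of 5 for the miR-30 family (3 with DESeq2 size factors, 2 with totals and 1 with TMM from arms over the floor), 2 of 9 for let-7 (0 over the list alone, and 0 in the other scalings), 1 of 2 for miR-34 and miR-449, 1 of 3 for miR-29 (2 with totals) and 0 of 3 for the miR-99a cluster (1 with totals). Of the 3 arms passing in the miR-23, miR-27 and miR-24 clusters, miR-27b-3p (0.69) was higher and miR-23a-3p (−0.67) and miR-27a-3p (−0.39) were lower in BicR. The arms passing for miR-17~92 and paralogues, miR-30, let-7, miR-34 and miR-449, and miR-29 were all lower in BicR in the main fit. On the androgen-repressed list 3 of 6 were higher. Over all arms 1 of these 6 passed (0 over the list alone), with 2 or 3 passing in the other scalings. These counts rest on the 0 h and 24 h libraries. Without BicR 0 h, 1 arm passed over all arms in each of the miR-200, miR-23 and miR-27 and miR-24, miR-30, miR-15 and miR-16, and miR-34 and miR-449 groups, and 0 in miR-17~92, let-7, miR-221 and miR-222 and the androgen-repressed list. Without LNCaP 0 h the counts were 1 for miR-30, miR-17~92 and miR-15 and miR-16, and 0 for let-7, miR-221 and miR-222 and the androgen-repressed list. Without either 24 h library they were the same as without LNCaP 0 h for these 6, and 0 for miR-34 and miR-449. Without LNCaP 6 h, 6 of miR-17~92, 3 of the androgen-repressed list and 2 of miR-221 and miR-222 passed.

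Markers of other cell types were counted as well. Of 9 stromal and muscle markers only miR-143-3p passed the floor. With 1 measured arm on a list, a p over the list alone is an unadjusted p. At 6 h it was 0.0401 (edgeR, 0.0543 with DESeq2 size factors), while the adjusted p over all arms was 0.889. As given above, the 6 h difference was lost without the BicR 6 h library. At 24 h the unadjusted p was 0.2 (edgeR, 0.000887 with totals), and the adjusted p over all arms was 0.609. Of 8 blood cell markers 0 passed the floor. Of 5 liver and neuron markers 3 passed it, miR-9-5p, miR-9-3p and miR-128-3p, and 0 were called at 24 h, while between lines 1 passed over all arms and 2 over the list alone (1 in the other scalings, and 0 either way without a 0 h or a 24 h library). Of the 2 basal prostate markers only miR-203a-3p was measured, an abundant arm at 1.19% of reads in LNCaP and 1.38% in BicR at 0 h. It was not called in any of the 3 tests (edgeR, unadjusted p = 0.387 at 24 h). With totals it was called as higher in BicR over all arms (edgeR, unadjusted p = 0.00311). The other marker, miR-205-5p, stayed under the floor.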

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

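The search for candidate loci and its limits were chosen after part of the counts had been seen. Among 3364 numbered candidate loci, which the comparisons leave out, 2 had at least 100 reads in a treated library and at least 3 times the level at 0 h in that line. The locus block4190985_cand (3′ arm) had 28 reads in LNCaP at 0 h, 186 at 6 h and 120 at 24 h, 6.08-fold (interval 4.07 to 9.4) and 3.73-fold (interval 2.46 to 5.85) the level at 0 h. In BicR, whose libraries differ in depth, it was 1.71-fold (interval 0.89 to 3.5) at 6 h and 0.742-fold (interval 0.393 to 1.5) at 24 h. The locus sblock11788_novel (5′ arm) had 290 reads in BicR at 24 h and 16 at 0 h, 3.88-fold (interval 2.35 to 6.89), and in LNCaP it was 1.38-fold (interval 0.79 to 2.48) at 24 h. At 6 h this second locus was 0.658-fold (interval 0.317 to 1.38) in BicR and 1.29-fold (interval 0.723 to 2.34) in LNCaP. No explanation of these loci was tested. A second search asked for arms over the floor that moved in opposite directions in the lines at both times. It required more than 0.2 on the log2 scale under all 4 scalings and intervals excluding no change, and no arm passed. Under the main scaling alone miR-190b-5p met these limits, at −0.31 and −0.55 in LNCaP at 6 h and 24 h. In BicR it was at 0.62 and 0.92.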

How the results depend on the processing

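Added after seeing the data were candidate loci together with named arms and TMM factors from arms over the floor. Counts of 2-fold arms depended most on the floor. With no floor they were 112 in LNCaP at 24 h, 88 in LNCaP at 6 h, 172 in BicR at 24 h, 233 in BicR at 6 h and 262 between the lines at 0 h, where few reads per arm set the ratios. With a floor of 50 CPM they were 0 in LNCaP at 24 h, 1 in BicR at 24 h, 4 in BicR at 6 h and 21 between lines at 0 h. In LNCaP at 24 h the count was 1 with totals, 1 with a prior count of 10 and 4 with candidate loci, which also gave 1 at 6 h. The other scalings and prior counts kept these counts within 1.5 times.

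The correlation of 24 h changes between lines was 0.160 with a floor of 1 CPM. Within LNCaP the 6 h and 24 h correlation was 0.686 with a floor of 50 and 0.476 with a floor of 1. The cause was not tested for any of these.

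At 24 h in both lines the calls were 2 with the DESeq2 Wald test and 2 with totals, and between 0 and 4 with 1 library left out. At 6 h they were 3 with totals and between 0 and 5 with 1 library left out. Between lines they ran from 43 to 139 with 1 library left out, and the other settings gave 80 to 132. Without the BicR 6 h library the 6 h difference of miR-143-3p in both lines turned to −0.135, and over all left-out libraries it ran up to 4.385. A lone library left at a time is assumed to vary like the others. Of 80 list medians, 63 kept their sign with totals and 72 with TMM from arms over the floor. The tests already pair libraries by cell line and by time, and without the time block 96 arms were called between lines. By replicate number no paired analysis was possible because each group has 1 library. Differences of 1.5-fold were often under what 1 library per time could show.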

Other observations

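Chosen after the results were seen were the tests of LNCaP RNA in the BicR 6 h library, both tests on the miR-99a cluster, the correlation with GC content, and the correlations with the other line. The BicR library at 6 h lay closer to LNCaP than the other BicR libraries did. The median absolute deviation of the log2 differences between lines was 0.36 at 6 h, 0.63 at 0 h and 0.60 at 24 h. Across 287 arms, the 6 h change in BicR correlated at r = 0.511 with the difference of LNCaP from BicR at 24 h, which shares no library with it. For the 6 h change in LNCaP toward BicR the same value was 0.198.

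For the wider spread of the BicR changes at 6 h than at 24 h, the values argue against depth and a linear GC trend. They argue against LNCaP RNA as the whole cause on a few arms only. The nearness to LNCaP was not recomputed after thinning or a GC correction, so depth and GC were not tested for it. After every library was thinned to 2223128 reads, the spread of the 6 h changes was still 1.42 times that of the 24 h changes. The bootstrap interval was 1.24 to 1.76, and the ratio before thinning was 1.56, which argues against depth. This interval, and those of the GC values below, are taken over arms, which are not independent replicates. They hold no spread between libraries. A linear GC trend is argued against by the correlation of the 6 h changes with GC content of the hairpin arm, at r = −0.0241 (interval −0.14 to 0.0928), where an r of about 0.64 is needed to bring the ratio down to 1.2. A correction on GC therefore moved little, left 1.59 (interval 1.28 to 1.9) and adds no evidence of its own. LNCaP RNA in this library as the whole cause is argued against by bounds that conflict. The arm miR-146a-5p allows a share of at most 5.5%, while miR-3647-3p needs at least 52.7% and miR-3607-3p 32.6%. The name miR-3647 is listed as an older symbol of a small nucleolar RNA gene. Every other arm examined needs at most 0.608%, so without miR-3647-3p and miR-3607-3p the test could not tell. Of a smaller share miR-10a-5p gave no sign, at 274, 283 and 256 CPM in BicR at 0 h, 6 h and 24 h. Its level in LNCaP at 6 h was 3236 CPM. Whether a share under 5.5% adds to the pattern was not tested. Library preparation and a transient response to DHT in BicR stay open, as untested.

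In the miR-99a cluster, opposite values of arms from 1 host gene could come from counting or scaling. The 9 let-7 family 5p arms together had a TMM-scaled log2 difference of −0.478 in LNCaP (interval −0.481 to −0.475). Their unscaled share of reads was 25.7% at 0 h and 20.5% at 24 h, a log2 difference of −0.33, so a transfer of reads between family members is argued against. The ratio of miR-99a-5p to let-7c-5p within a library was higher by 0.976 (interval 0.961 to 0.991), and by 0.602 in BicR. No scaling can alter a ratio within a library, so scaling did not make the gap between the arms. The ratio repeats the values that raised the question, and does not test whether the opposite signs hold under each scaling. No biological explanation was tested, and what lies behind the difference stays open.

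The miR-143-3p reads of the LNCaP 24 h and BicR 6 h libraries might come from stromal or muscle cells. As a test of RNA from stromal or muscle cells, other markers with 10 or more reads in both libraries were counted, and there was 1, miR-199a-3p, at 1.39-fold and 0.909-fold the mean of the line's other libraries. With fewer reads, miR-1-3p had 28 and 9 (1.57-fold and 9.82-fold) and miR-199a-5p 8 and 2, while miR-145-5p had 0 and 1, miR-206-3p 1 and 0, and miR-214-3p and miR-133a-3p 0 in both, against 632 and 583 of miR-143-3p. The near-absent markers speak against such RNA, but the reads that it would bring per read of miR-143-3p are not known here. Stromal RNA, a response of the cells and other sources of these reads cannot be told apart. Of these only stromal RNA was examined.

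For the 108 arms called between lines, 1 of the 10 ways to divide the 6 libraries into 3 and 3 gave as many calls, the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 can be had. Every other split mixes the lines, so the line difference enters the residual spread and few or no calls can result. The splits therefore cannot tell how many calls chance would give.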
